A study of Bos taurus with 6 samples.

How the data were processed

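Small RNA of 3 bovine adipocyte and 3 bovine preadipocyte samples was sequenced. Per the labels' protocols, cells grew in F12/DMEM with 10% fetal bovine serum and 1% antibiotics, RNA was extracted with Trizol, segments of 18 to 30 nt were cut from a gel, adapters were ligated to both ends, and PCR products of 100 to 120 bp were kept. Bowtie2 is named in the submitters' processing notes, with no version. The genome build, the miRNA annotation release and the rule for reads that match several miRNAs were not given in the sources used here.

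The deposited table holds 2213 rows and, per the file headers, a count and a TPM value for each of the 6 libraries. The count columns are whole numbers of reads that the authors had not normalized. The deposited TPM values were found to be the count divided by 1 constant per library, so that they carry no division by length, and a count of 0 is written as 0.001. The table's rows hold 81.1% to 86.4% of the library totals that this constant implies. The rows are 771 known miRNAs, 108 predicted miRNAs, 803 Rfam rows (179 of them miRNA families), 527 predicted piRNAs and 4 rows of reads by genome feature (exon, intron, intergenic, repeat). The 879 known and predicted miRNA rows hold 74.5% to 86.4% of the table's reads. The 4 genome-feature rows name no gene and stayed out of library sizes and tests, with shares of the table of 10.2% ± 1.91 in adipocytes and 14.2% ± 7.73 in preadipocytes (SD, n = 3). The Rfam and piRNA rows were also left out of the miRNA test, since the sources used here do not say whether an Rfam miRNA family shares reads with the miRNA rows.

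Groups were taken from the cell type in the labels. The design, the rule for named miRNAs, the miRNA lists and most alternatives were fixed before the data were examined. The table's columns were matched to samples by the sample titles in their names.

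Differential abundance was tested on the deposited counts of the known and predicted miRNAs with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr at its defaults, glmQLFit and glmQLFTest, group as the only term, two-sided), with Benjamini-Hochberg (BH) adjustment and a threshold of 0.05. The filter left 365 known and 49 predicted miRNAs. Lists of miRNAs were tested against all other tested miRNAs with camera of limma 3.58.1 on log2 CPM, with its preset correlation of 0.01 and again with an estimated correlation, over the 17 lists with at least 3 tested members. A miRNA belonged to a list when its precursor did, with both arms counted. Counts of list members past the threshold are given over all miRNAs and adjusted over the list alone. Arm usage was tested with limma on log2 of 5p over 3p counts, 0.5 added to each, for precursors whose arms both had a mean of at least 10 counts per library. Shares of reads were compared with exact two-sided permutation tests in SciPy 1.17.1, which cannot go below 0.1 with 3 libraries against 3. Tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15 and plots drawn with matplotlib 3.10.9.

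The miRNAs named are the known ones past the threshold with a mean of at least 10 CPM and no overlap between the groups (up to 12 each way), the 5 most abundant, up to 4 members of each list (the 2 most abundant and the 2 with the smallest p; every member of lists with fewer than 3), up to 5 precursors with changed arm usage, and the arms of miR-149. Not every miRNA this rule takes is described. Others are named as chosen after their values were seen.

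Reads of near-identical miRNAs can be divided by the counting in ways the table does not record. Counts were therefore also summed by the family in the table's description column, and over known miRNAs whose genes overlap in the RefSeq gene table of assembly ARS-UCD2.0, which was used for names and overlap only because the table's build is not stated. Of 702 known precursor names, 685 matched a gene there, and 26 pairs of miRNA genes at 21 loci overlapped.

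The steps were tested on simulated data for the adipocyte against preadipocyte comparison. For the miRNA and list tests these were drawn from the means and library sizes of these libraries. Over 392 miRNAs the edgeR test recovered 18.4% of 2-fold, 61.7% of 4-fold, 93.9% of 8-fold and 95.7% of 32-fold changes and called 3 of 201 unchanged miRNAs. A simulated shift of 1 log2 unit in the DLK1-DIO3 list, over 387 miRNAs, gave camera BH-adjusted p-values of 6.70e-17 with the preset and 0.0117 with an estimated correlation, and no shift, over 397 miRNAs, gave 0.727 with the preset. The simulated members varied independently of each other, while the correlation estimated for the list in the data was 0.22. These draws therefore cannot show how often the preset test calls the list when its members vary together. The arm test recovered 4 of 8 changed precursors of 29, with 0 false calls. Its counts were drawn from the row means with a fixed dispersion, without library sizes and without reads that switch between names. They therefore cannot show how the arm test behaves with the spread of these libraries. The biological coefficient of variation between replicates was 0.61.

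Alternatives covered other scalings (RLE, upper-quartile, library totals alone), DESeq2 1.42.0, limma-voom, limma-trend on log2 of the deposited TPM plus 1, other filters, known miRNAs alone, a 2-fold minimum, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were family sums, merged overlapping genes, library sizes without miR-21-5p, the totals implied by the TPM, and the share of genome-feature reads as a covariate. No genome coordinates are given.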

Results

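Small RNA of 6 samples of cultured bovine cells was compared, 3 of preadipocytes and 3 of adipocytes. Preadipocytes are the committed precursors of fat cells, and the adipocytes were the same kind of culture after induction with insulin, dexamethasone, rosiglitazone and IBMX. The cells came from Holstein cattle and were used at passage 4 to 6. The length of the induction was not given in the sources used here. The table of the 6 libraries held 19292757 reads in the smallest library and 25801117 in the largest. Known and predicted microRNAs (miRNAs) took 15035059, 15111228 and 19123498 reads in adipocyte replicates 1, 2 and 3 and 17440838, 14525284 and 22283754 reads in preadipocyte replicates 1, 2 and 3. At this depth a count of 0 allowed a level of up to 0.142 to 0.244 CPM (counts-per-million of miRNA reads after TMM scaling), depending on the library. These limits cover counting error only and hold for the known miRNAs. Among predicted miRNAs the smallest count above 0 was 10, so a 0 there may stand for any count below 10. Nothing in the labels says that the replicates came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. Levels below are CPM of the library size after scaling with edgeR's TMM factors, as mean ± SD with n = 3 per group, and differences as log2 of adipocytes over preadipocytes. All miRNAs carry the species prefix bta- in the table, which is left out here.

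The small RNA of both cell states was dominated by miR-21-5p, a miRNA abundant in many cultured mesenchymal cells. It took 68.2% ± 5.23 of the miRNA reads in adipocytes and 79% ± 1.13 in preadipocytes (n = 3 each), and every adipocyte library (at most 74.1%) lay below every preadipocyte library (at least 77.9%). The 10 most abundant miRNAs together took 88% ± 2.19 in adipocytes and 93% ± 0.225 in preadipocytes. Both differences had a two-sided exact permutation p of 0.1, the smallest that 3 libraries against 3 can give. The next most abundant miRNAs were let-7i, miR-143, miR-3600 and miR-99a-5p, none of which passed the test between the groups. The level of let-7i was 36130 ± 4768 CPM in adipocytes and 46811 ± 10722 CPM in preadipocytes, and that of miR-143, a smooth muscle and mesenchymal miRNA, was 24214 ± 4814 and 30171 ± 7966 CPM. The log2 differences of let-7i (-0.37) and miR-143 (-0.32) turned positive when libraries were scaled by their totals alone (0.24 and 0.32). The reads of miR-3600, at 22609 ± 1473 and 22501 ± 4537 CPM, are uncertain because its gene overlaps that of miR-22, and the sum over that locus differed by 0.01 (SE 0.19). On the TMM scale miR-21-5p itself differed by -0.82 (SE 0.23), which missed the threshold with an edgeR adjusted p (Benjamini-Hochberg, BH) of 0.0637. The difference of bta-miR-21-5p passed with a minimum of 10 CPM (-1.03), without adipocyte replicate 3 (-1.24) and with the share of exon, intron, repeat and intergenic reads as a covariate (-0.88, a test added after seeing the data), and was -0.21 with library totals alone.

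Reads outside the miRNA rows set the preadipocyte libraries apart from each other. Reads in the exon, intron, repeat and intergenic rows made up 10.2% ± 1.91 of the table in adipocytes and 14.2% ± 7.73 in preadipocytes (exact permutation p = 0.4, n = 3 each). They were 18.5% and 18.9% in preadipocyte replicates 1 and 2 and 5.29% in preadipocyte replicate 3. The same library stood apart on the second principal component of the miRNA levels, which held 24.2% of the variance, while the first (44.1%) separated the groups. Ribosomal RNA took 0.784% ± 0.025 of the reads in adipocytes and 1.2% ± 0.635 in preadipocytes (exact permutation p = 0.4).

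The design asked which miRNAs differ between preadipocytes and adipocytes. The largest increase was that of miR-199a-3p, a mesenchymal miRNA, from 16.2 ± 6.83 CPM in preadipocytes to 6757 ± 931 CPM in adipocytes, and the largest decrease among known miRNAs past the threshold and at or above 10 CPM was that of miR-3604, from 3375 ± 1082 to 28.9 ± 18.9 CPM. The genes of these 2 miRNAs overlap, and their summed reads differed by 1.00 on the log2 scale (SE 0.29, edgeR BH-adjusted p = 0.0666). Adipocytes also held more miR-33b, which lies in an intron of the sterol regulator SREBF1, more miR-148a, described as favouring adipocyte differentiation, and more of the imprinted-domain miRNAs miR-410, miR-376a and miR-376b. They held less miR-24-3p, of the miR-23/27/24 clusters, and less miR-181c.

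In edgeR's quasi-likelihood test with BH adjustment, 26 of 414 tested miRNAs passed an adjusted p of 0.05, 16 higher and 10 lower in adipocytes. Of these, 15 of the higher and 8 of the lower ones were known miRNAs and the others were predicted ones. The threshold was passed only by miRNAs that differed at least 2-fold, and 9 of the 26 had a mean below 10 CPM. Without adjustment, 141 miRNAs had p below 0.05. On the TMM scale the groups did not overlap for 185 miRNAs (44.7%), where chance gives 10% with 3 libraries against 3.

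Among the known miRNAs at or above 10 CPM, 10 rose in adipocytes. The log2 difference of miR-199a-3p was 8.70 (SE 0.47, edgeR BH-adjusted p = 2.62e-04). The next was miR-33b at 5.67 (SE 1.14, edgeR BH-adjusted p = 0.0381), with 959, 1276 and 61 reads in adipocyte replicates 1, 2 and 3 and 5 to 14 reads in the preadipocyte libraries. A log2 difference of 3.43 (SE 0.46, edgeR BH-adjusted p = 0.0198) was found for miR-708, at 324 ± 66.4 CPM in adipocytes and 30.1 ± 15.9 CPM in preadipocytes. The level of miR-148a was 1378 ± 236 CPM against 430 ± 130 CPM, a log2 difference of 1.68 (SE 0.32, edgeR BH-adjusted p = 0.0309), and stayed at 1.68 after its reads were summed with those of the overlapping miR-148d gene. For miR-449a, a relative of the p53-responsive miR-34, the levels were 279 ± 44.6 and 87.7 ± 25.6 CPM (log2 difference 1.67), and for miR-15a, which targets the survival gene BCL2, 183 ± 48.8 and 62.4 ± 13.6 CPM (1.56). The most abundant of the 10 after miR-199a-3p was miR-100, at 4660 ± 445 CPM in adipocytes and 1904 ± 411 CPM in preadipocytes (1.29). The adjusted p-values of miR-449a, miR-15a and miR-100 in edgeR's test (BH) were 0.0347, 0.0481 and 0.0293.

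Below the preadipocyte level were 4 known miRNAs at or above 10 CPM. They were miR-3604 with a log2 difference of -6.87 (SE 0.80, edgeR BH-adjusted p = 0.0134), miR-1296 with -2.17 (SE 0.40, edgeR BH-adjusted p = 0.0293), miR-24-3p with -1.78 (SE 0.28, edgeR BH-adjusted p = 0.0242) and miR-181c with -1.58 (SE 0.35, edgeR BH-adjusted p = 0.0481). The level of miR-24-3p was 2548 ± 653 CPM in adipocytes and 8739 ± 1517 CPM in preadipocytes, and those of miR-181c were 23.8 ± 3.82 and 71.4 ± 20 CPM. Summed over their families, in which reads can be shared between near-identical members, miR-15a (0.95), miR-100 (0.79) and miR-181c (-0.16) no longer passed, with edgeR BH-adjusted p of 0.0603, 0.052 and 0.663. The family sum that holds bta-miR-199a-3p differed by 2.12 (edgeR BH-adjusted p = 0.0094), against 8.70 for that miRNA alone. That sum does not include miR-3604, which is placed in another family. The count of 26 was 1 without adipocyte replicate 1, adipocyte replicate 2 or preadipocyte replicate 2. It was 4 without preadipocyte replicate 1, 8 without adipocyte replicate 3 and 148 (64 higher, 84 lower) without preadipocyte replicate 3. With known miRNAs alone it was 59, and with DESeq2 116. DESeq2 was run without the low-count filter, on 869 miRNAs against 414, so the rows tested changed along with the tool. The balance of 16 higher and 10 lower depended on scaling, with 15 higher and 34 lower under upper-quartile factors and 88 and 9 with library totals alone, where the median of all miRNAs moved from -0.02 to -0.31 and 0.62. It also differed with the rows tested, at 15 and 21 with a minimum of 10 CPM and 27 and 32 with known miRNAs alone. With limma on the deposited TPM, which changes the tool and the transform along with the scaling, it was 110 and 12 (median 0.39).

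**Figure D1:**
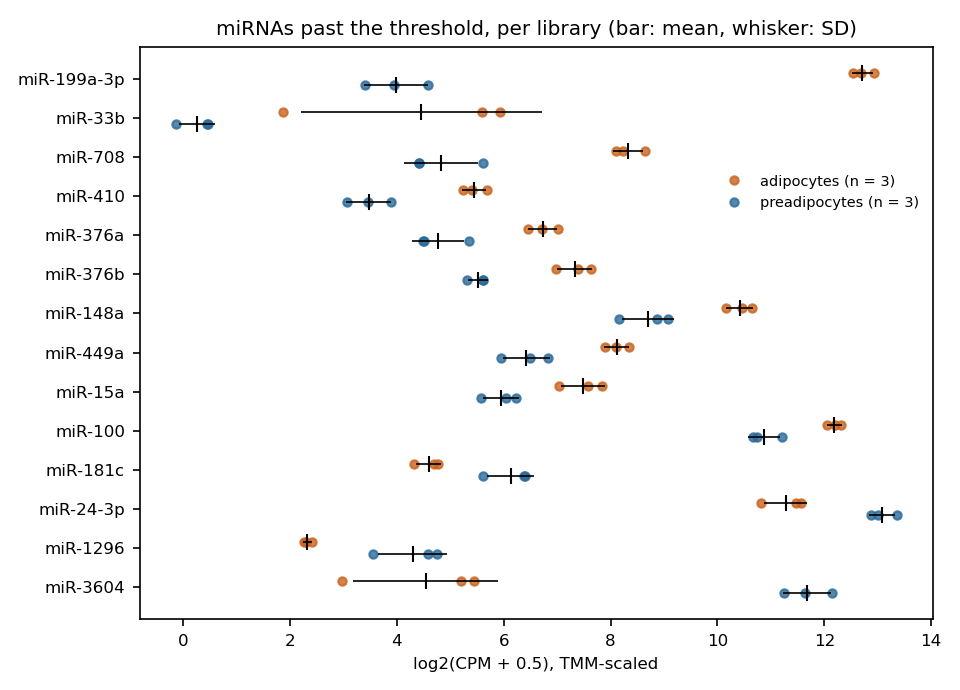
Level of each known miRNA past the threshold and at or above 10 CPM, as log2(CPM + 0.5) after TMM scaling, with 1 point per library (3 adipocyte, 3 preadipocyte), a bar at the mean and a whisker of 1 SD. Adipocyte and preadipocyte points do not overlap for any of the 14 miRNAs, and the adipocyte libraries of miR-33b spread from 3.12 to 60.4 CPM.

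**Figure D2:**
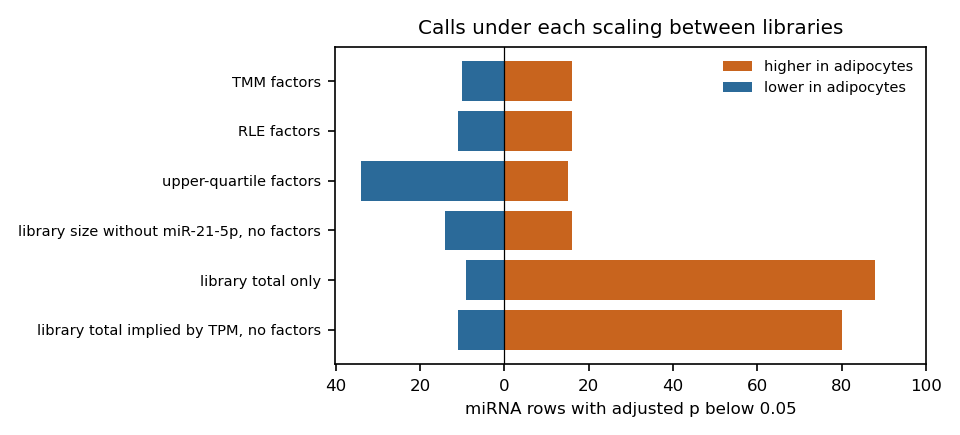
Number of miRNA rows with adjusted p below 0.05 that were higher (right) or lower (left) in adipocytes, under 6 ways to scale the libraries. TMM gave 16 higher and 10 lower and library totals alone gave 88 and 9.

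Of the miRNAs described as promoting adipocyte differentiation, 23 were tested, and miR-199a-3p and miR-148a rose, both also when adjusted over the list alone, though miR-199a-3p did not pass with its reads merged with those of the overlapping genes (0.90, edgeR BH-adjusted p = 0.0603). None of that list passed as lower. Estimates were positive for 15 of the 23, and among the negative ones were miR-21-5p (-0.82) and miR-210 (-1.88). The list's median log2 difference was 0.55 and camera's test of the list against all other miRNAs gave a BH-adjusted p of 0.168. Among 26 miRNAs described as restraining differentiation, 0 passed the test over all miRNAs or adjusted over the list alone, and camera's BH-adjusted p was 0.638. Of these, 16 had positive estimates, and the median log2 difference was 0.23. The 2 with the smallest p, miR-149-5p and miR-145, had negative estimates. The restraining miR-149-5p was at 402 ± 46.1 CPM in adipocytes and 1472 ± 840 CPM in preadipocytes, a log2 difference of -1.87 (SE 0.50, edgeR BH-adjusted p = 0.0637). For miR-145, co-transcribed with miR-143, the levels were 1292 ± 579 and 4027 ± 1588 CPM (-1.64, SE 0.45, edgeR BH-adjusted p = 0.0637). On the TMM scale all 3 libraries of each group lay apart for both. Per total miRNA reads without these factors the groups overlapped. For miR-149-5p, preadipocyte replicate 3 held 9003 of 22283754 reads and adipocyte replicate 1 held 7232 of 15035059. For miR-145, adipocyte replicate 1 held 39284 of 15035059 reads and preadipocyte replicate 2 held 27009 of 14525284. The let-7 family, which holds many of the restraining miRNAs, had 0 of 10 tested members past the threshold and 0 adjusted over the list alone (camera BH-adjusted p = 0.496), with let-7a-5p at 20207 ± 2969 and 13892 ± 3578 CPM.

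The miRNAs hosted in introns of lipid and mitochondrial regulators had positive estimates for all 5 tested members, with a median log2 difference of 1.24. Of these, miR-33b rose, and 3 were higher when adjusted over the list alone. Its sister miR-33a, in an intron of SREBF2, was at 337 ± 100 CPM in adipocytes and 101 ± 41.6 CPM in preadipocytes (1.74, SE 0.40, edgeR BH-adjusted p = 0.0539), and miR-378, in an intron of PPARGC1B, at 4449 ± 1715 and 2331 ± 1075 CPM (0.93, edgeR BH-adjusted p = 0.177). The sum of both miR-33 sequences, which are nearly identical, rose by 2.12 (edgeR BH-adjusted p = 0.0318). Camera's BH-adjusted p for the list was 0.0513, which missed the threshold, and 0.525 with an estimated correlation.

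In the miR-23/27/24 clusters, miR-24-3p fell and the other 7 tested members did not pass, among them miR-23a at 5813 ± 760 and 10489 ± 2155 CPM (-0.85, edgeR BH-adjusted p = 0.0645). Adjusted over the list alone, 3 were lower, and camera's BH-adjusted p was 0.168. The third of these, miR-23b-3p, named after its values were seen, rests on preadipocyte replicate 1 (3245 CPM, against 32.9 and 50.7 CPM in the other preadipocyte libraries), and its log2 difference was -6.47 with all libraries and -1.74 without that one. In the miR-15/16 family miR-15a rose while miR-503-5p, of the same extended family, was at 11.2 ± 0.758 and 47.3 ± 36.8 CPM (-2.08, edgeR BH-adjusted p = 0.0637). The preadipocyte level of miR-503-5p was 89.8 CPM in replicate 3 and 25.9 and 26.1 CPM in the others, and without replicate 3 the difference was -1.23 and passed (edgeR BH-adjusted p = 0.0204). Adjusted over the list alone, 1 of its 10 members was higher and 1 lower, and camera's BH-adjusted p was 0.519. Of 11 tested members of the miR-17-92 clusters, 0 passed over all miRNAs or adjusted over the list alone (camera BH-adjusted p = 0.728), with miR-92a at 1719 ± 142 and 3212 ± 477 CPM (edgeR BH-adjusted p = 0.0588). The miR-30 family had 0 of 7 and the miR-130 family 0 of 3 members past either adjustment (camera BH-adjusted p = 0.543 and 0.918), and miR-30e-5p stood at 111 ± 42.9 and 42.4 ± 12 CPM. Of the collagen-targeting miR-29 family, 0 of 4 passed over all miRNAs and miR-29b, at 680 ± 476 and 120 ± 36 CPM, was higher adjusted over the list alone (camera BH-adjusted p = 0.496). That difference rests on adipocyte replicates 1 and 2 (874 and 1029 CPM), since adipocyte replicate 3, at 138 CPM, lay within the preadipocyte range of 78.4 to 142 CPM. In the miR-181 family miR-181c fell, also adjusted over the list alone, and the other 3 did not pass (camera BH-adjusted p = 0.206).

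Among 13 tested miRNAs abundant in mesenchymal cells and fibroblasts, miR-199a-3p (not past the threshold with merged reads, as above) and miR-100 rose, and adjusted over the list alone 3 were higher and 2 lower (camera BH-adjusted p = 0.179). Of 11 described in brown adipocytes, only miR-133a passed the threshold over all miRNAs, from 5.99 ± 1.46 CPM in preadipocytes to 1.63 ± 0.344 CPM in adipocytes (-1.88, SE 0.34, edgeR BH-adjusted p = 0.0293), or -1.90 after its reads were summed with those of the overlapping miR-133c gene. Adjusted over that list alone, 2 were higher and 1 lower (camera BH-adjusted p = 0.543), with miR-193a at 143 ± 50.2 and 46 ± 13.8 CPM and miR-196a at 747 ± 142 and 414 ± 94.7 CPM. Separate rows for the 5p and 3p arms of miR-193a, looked up after the values were seen, differed by -0.17 and 3.20. The 5 tested miRNAs of the HOX clusters, which include miR-196a, gave 0 past either adjustment (camera BH-adjusted p = 0.543). In lists with fewer than 3 tested members, miR-449a rose and miR-34a (7275 ± 659 and 5311 ± 1466 CPM) did not pass. Neither did miR-221 (841 ± 287 and 935 ± 335 CPM), miR-222 (925 ± 243 and 1519 ± 990 CPM), or the CREB-driven miR-132 and miR-212, whose group means were below 1 CPM in both groups.

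The miRNAs of the imprinted DLK1-DIO3 domain, which are transcribed from the maternal chromosome, lay higher in adipocytes as a group. Of 46 tested members, 43 had a positive estimate, 7 rose, 0 fell and 39 did not pass, and adjusted over the list alone 13 were higher. The list's median log2 difference was 1.12. The examples were miR-410 at 43.4 ± 7.24 and 10.9 ± 3.25 CPM (1.99, SE 0.35, edgeR BH-adjusted p = 0.0293), miR-376a at 107 ± 20.8 and 28 ± 10.4 CPM (1.93, SE 0.37, edgeR BH-adjusted p = 0.0341), miR-376b at 163 ± 36.2 and 45.6 ± 5.61 CPM (1.84, SE 0.31, edgeR BH-adjusted p = 0.0263) and miR-487a at 16.2 ± 3.72 and 3.77 ± 0.725 CPM (2.10, SE 0.33, edgeR BH-adjusted p = 0.0242). At a lower level, miR-154a differed by 2.60 (2.43 ± 0.521 and 0.395 ± 0.0243 CPM). The most abundant members did not pass, with miR-411a at 1533 ± 277 and 750 ± 78.2 CPM (edgeR BH-adjusted p = 0.0546) and miR-127 at 1300 ± 177 and 782 ± 64.9 CPM (edgeR BH-adjusted p = 0.0763). Camera with its preset correlation placed the list 1.32 above the other miRNAs (BH-adjusted p = 9.75e-11), the only 1 of 17 lists past the threshold. With an estimated correlation between members of 0.22, camera's BH-adjusted p was 0.525 and the list was not called. The number of members past the threshold was 0 without adipocyte replicate 1 or 2 or preadipocyte replicate 1 or 2, 1 without adipocyte replicate 3 and 27 without preadipocyte replicate 3, the library with 5.29% of reads in the exon, intron, repeat and intergenic rows.

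**Figure D3:**
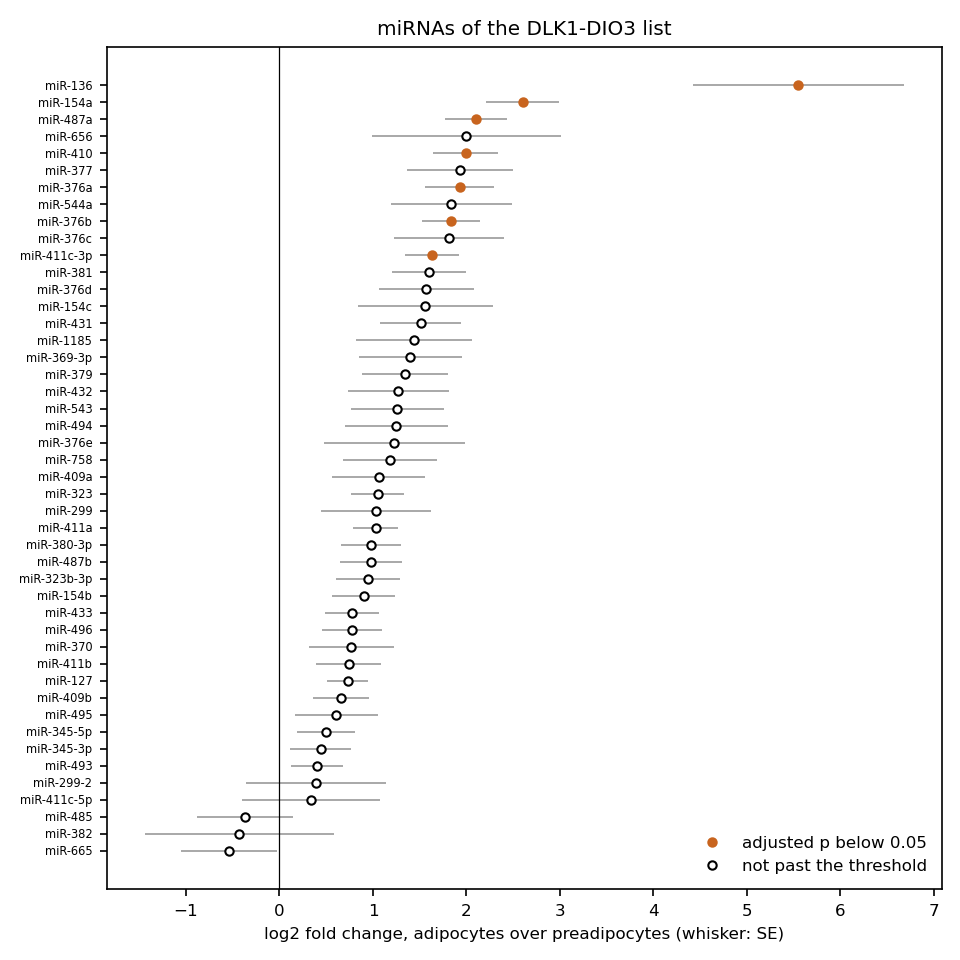
Log2 difference (adipocytes over preadipocytes, 3 libraries each) of the 46 tested miRNAs of the DLK1-DIO3 list, with whiskers of 1 SE. Filled points are the 7 members with an adjusted p below 0.05, and 43 of the 46 points lie right of 0.

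No tested marker of another cell type rose in adipocytes. The muscle list had 3 tested members, of which miR-133a fell, also adjusted over the list alone (camera BH-adjusted p = 0.638). Of the 5 neural miRNAs, miR-129-3p fell, also adjusted over the list alone, from 1.9 ± 0.878 CPM to 0.133 ± 0.0775 CPM, or 1 to 4 reads per adipocyte library, and camera's BH-adjusted p was 0.168. The neural miR-7 was at 1016 ± 62 CPM in adipocytes and 1841 ± 666 CPM in preadipocytes (edgeR BH-adjusted p = 0.103). The endothelial miR-126-3p was at 50.6 ± 14 and 232 ± 186 CPM (-2.20, SE 0.60, edgeR BH-adjusted p = 0.0637), its partner miR-126-5p at 1.02 ± 0.194 and 3.76 ± 4.69 CPM, the red-cell miR-451 at 0.601 ± 0.362 and 3.06 ± 1.31 CPM (edgeR BH-adjusted p = 0.0637) and the hypoxia-induced miR-210 at 3.01 ± 1.77 and 11.1 ± 5.74 CPM (edgeR BH-adjusted p = 0.0955). Preadipocyte replicate 3 held 446 CPM of miR-126-3p and 9.17 CPM of miR-126-5p, against 112 and 137 CPM and 1.3 and 0.814 CPM in the other preadipocyte libraries. Without it the differences were -1.32 (edgeR BH-adjusted p = 0.0352, past the threshold) and -0.05, where all libraries gave -2.20 and -1.88. That of miR-451 was -2.33, and -2.94 without adipocyte replicate 3. Adjusted over the list alone, 1 miRNA of each of these lists (endothelial, blood and hypoxia) was lower. None of the epithelial miRNAs reached the level needed for testing.

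Arm usage was compared within each library, which leaves scaling out. A precursor gives a miRNA from its 5p and its 3p arm, and of 32 precursors with both arms counted only miR-199a changed its ratio. Its 5p arm exceeded the 3p arm by 7.73 ± 0.33 on the log2 scale in preadipocytes and lay below it, at -0.57 ± 0.40, in adipocytes (n = 3 each), a difference of -8.30 (SE 0.41, limma BH-adjusted p = 2.26e-05). The 5p arm itself differed by 0.47 (SE 0.25). The 3p arm is the one whose reads moved opposite to miR-3604. Without adjustment 6 precursors had p below 0.05, and for 9 the groups did not overlap.

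Reads of similar miRNAs were also divided unevenly between libraries of the same group. The nearly identical miR-27a-3p took 81.7% of its summed reads with miR-27b in adipocyte replicate 2 and 84.3% in preadipocyte replicate 1, and 11.4% to 14.4% in the other 4 libraries. For miR-30f and miR-30c, miR-30f took 92.1% in adipocyte replicate 3 and 89.8% in preadipocyte replicate 3, and at most 0.54% in the others. For miR-199a-3p and miR-3604 the division followed the groups, with miR-199a-3p at 99.4% to 99.9% of their sum in adipocytes and 0.417% to 0.516% in preadipocytes. The levels of these 6 miRNAs taken singly are therefore uncertain. These 3 pairs were chosen after their values were seen.

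**Figure D4:**
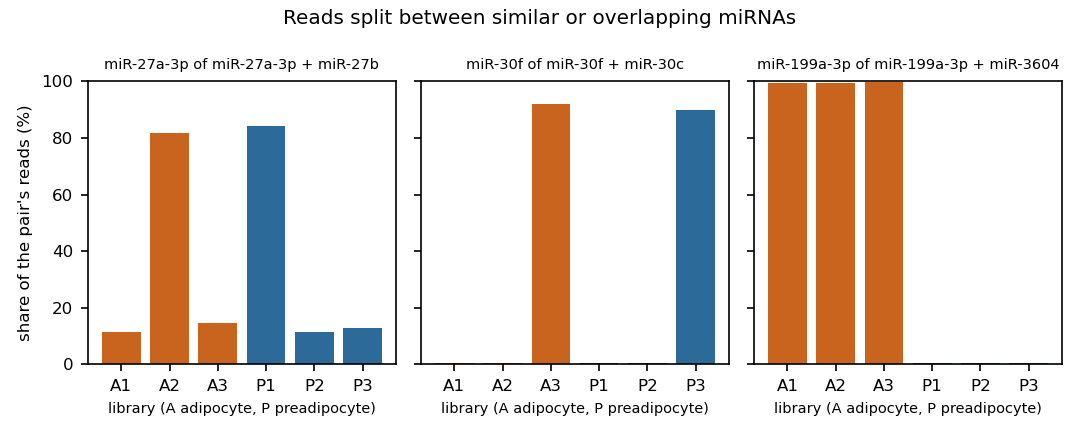
Share of a pair's reads (percent, 1 bar per library) counted for the first miRNA of 3 pairs with similar sequence or overlapping genes. The first 2 pairs switch in 1 library of each group and the pair miR-199a-3p and miR-3604 switches between the groups.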

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

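The test of the Rfam rows was chosen after their shares were seen. Reads that the table assigns to Rfam miRNA families, which no comparison above uses, made up 9.96% ± 0.627 of the table in adipocytes and 4.87% ± 2.02 in preadipocytes (n = 3 each), a ratio of 2.04. The 3 adipocyte libraries (9.27% to 10.5%) all lay above the 3 preadipocyte libraries (3.46% to 7.19%), with an exact permutation p of 0.1, the smallest possible here. The mir-21 family row held 66.1% of these reads.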

How the results depend on the processing

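Family sums, merged overlapping genes, library size without miR-21-5p, the totals implied by the TPM and the covariate were added after seeing the data. The number of miRNAs called (26) became 49 with upper-quartile factors, 97 with library totals alone, 116 with DESeq2, 59 with known miRNAs alone, 122 with limma-trend on the TPM, 91 with the totals implied by the TPM and 63 with the covariate, and ranged from 1 to 148 when 1 library was left out. DESeq2 was run without the low-count filter, so its values reflect other rows as well as another tool. It stayed within 1.5 times of 26 with RLE factors, limma-voom, no filter, a minimum of 10 CPM, a 2-fold minimum, family sums, merged genes and library size without miR-21-5p. Of the 18 called miRNAs named above, all 18 kept their call under DESeq2, RLE factors, known miRNAs alone, the covariate and without preadipocyte replicate 3, and 17, 17, 14, 15 and 17 lost it without adipocyte replicates 1, 2 and 3 and preadipocyte replicates 1 and 2. These fits have fewer libraries, and why leaving out preadipocyte replicate 3 added calls was not tested. None of the 18 changed sign. The call of bta-miR-199a-3p held in each of these settings, all of which kept its reads apart from those of miR-3604. The family sum that holds it differed by 2.12, against 8.70 for that miRNA alone. That sum also leaves out miR-3604, which is placed in another family. These settings therefore cannot tell whether reads were divided between these names. The call was lost when the reads of bta-miR-199a-3p were merged with those of the overlapping genes (0.90). The family sum that holds bta-miR-33b and the more abundant miR-33a also differed by 2.12 and passed, against 5.67 for bta-miR-33b alone. Without the low-count filter 6 calls were lost, with family sums 4, with limma-voom 3, with upper-quartile factors 2 and with library totals 1. Of the 30 miRNAs named above as not called, 15 passed with DESeq2, 11 with the TPM, 10 with library totals, 10 with the totals implied by the TPM, 9 with known miRNAs alone, 9 with the covariate, 7 with a minimum of 10 CPM, 6 with upper-quartile factors, 4 with limma-voom and 3 with family sums, each in the same direction. Without preadipocyte replicate 3 it was 11 and without adipocyte replicate 3 it was 2.

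The number of lists called (1) was 0 with an estimated correlation, 2 with RLE factors, 4 with no filter, 2 with merged genes and 1 to 2 with 1 library left out. Beyond the DLK1-DIO3 list, the added list was that of lipid-regulator introns and, with no filter, also the promoting and mesenchymal lists. Arm usage gave 1 precursor and the share of the top miRNAs a lower value in adipocytes under every alternative run. Cause not stated here was not tested.

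Signs that turned, all for miRNAs not called, were as follows. With library totals, the TPM and the totals implied by the TPM, let-7i became 0.24, 0.21 and 0.19, miR-143 0.32, 0.26 and 0.24, and miR-221 0.45, 0.40 and 0.41. With the TPM miR-222 became 0.12. With family sums, the whole let-7 family that holds let-7i differed by 0.27, against -0.37 for let-7i alone, which is no change of sign of let-7i itself. Without adipocyte replicate 2 and preadipocyte replicate 1, miR-221 became 0.11 and 0.17. With 1 library left out it ranged from -0.45 to 0.17. For bta-miR-3600 (0.01) the values were -0.02 with RLE factors, -0.28 with upper-quartile factors, -0.20 with a minimum of 10 CPM, -0.03 with known miRNAs alone, -0.04 with the covariate, and -0.04, -0.19 and -0.17 without adipocyte replicates 1 and 3 and preadipocyte replicate 2, in a range of -0.19 to 0.14 with 1 library left out.

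The labels do not say whether shared replicate numbers pair the samples. Same-numbered libraries had deviations correlated at 0.04, -0.31 and 0.02, and no library correlated best with its own number. These values give no sign of pairing, but so few libraries cannot exclude it. With the replicate number as a block, 1 miRNA and 2 lists were called, and 17 of the 18 called miRNAs named above lost their call. Other pseudocounts and filters planned for a table of normalized values alone were not run, since counts were given. With 3 libraries per group the simulated 2-fold changes were recovered in 18.4% of cases, so smaller differences were mostly not detectable.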

Other observations

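The tests on Rfam families, on the summed reads of miR-199a-3p and miR-3604, on family sums, on the list's median under other scalings, on library sizes without miR-21-5p, on the median of all miRNAs, on the covariate and on the correlation in other splits were chosen after seeing the data, and the miRNAs named for single libraries after their values were seen. The Rfam miRNA family rows gave 3 of 92 tested families past edgeR's BH-adjusted threshold and 30 with unadjusted p below 0.05. The mir-133 family fell by 1.92 on the log2 scale (SE 0.30, edgeR BH-adjusted p = 0.0265), the mir-24 family fell by 1.31 (SE 0.25, edgeR BH-adjusted p = 0.0457) and the mir-199 family rose by 1.01 (SE 0.20, edgeR BH-adjusted p = 0.0457). The mir-33 family, which did not pass, differed by 1.91. Across 67 families matched by name, the Rfam difference and the difference of the summed miRNA rows had Pearson r = 0.62 and Spearman rho = 0.62. Both kinds of row come from the same libraries, and in the other 9 splits of the 6 libraries into 3 and 3, r was 0.34 to 0.65 and rho 0.36 to 0.61, with r at least as high as the real one in 4 of the 10 splits. The correlation is therefore no evidence for a difference between the groups. Whether both kinds of row share reads was not given in the sources used here. Of the 67 families, 49 had the same sign in both kinds of row. Among those that went opposite ways were mir-21, at 0.37 in the Rfam row and -0.59 in the summed miRNA rows, and mir-146, at 1.24 and -2.39. Each value was scaled on its own kind of row.

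Preadipocyte replicate 3 held miRNAs that the other libraries almost lacked. The pluripotency-associated miR-302a had 162 reads there and 0 to 5 in each other library, and miR-302d had 175 against 3 to 17. The same library had 6011 CPM of miR-424-5p, against 917 to 1385 CPM in the other 5. In preadipocyte replicate 1, miR-23b-3p stood at 3245 CPM, against 3.47 to 50.7 CPM elsewhere. In adipocyte replicate 3, miR-33b (3.12 CPM) and miR-136 (1.74 CPM) lay far below adipocyte replicates 1 and 2 (47.5 and 60.4 CPM, and 26.9 and 26.2 CPM), as did miR-29b (138 CPM, against 874 and 1029 CPM).

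The increase of miR-199a-3p (8.70) and the decrease of miR-3604 (-6.87) are the largest among known miRNAs past the threshold and at or above 10 CPM, and RefSeq places both miR-3604 genes over miR-199 genes. When their reads were summed the log2 difference was 1.00 (SE 0.29). The 1.01 of the mir-199 Rfam row was scaled on the Rfam rows alone and cannot be set beside it. As a share of all table reads that row was 3.65 times as high in adipocytes as in preadipocytes. Given the sum, a candidate explanation for most of both changes is a switch of name in the counting. Reads of the shared locus would be counted under 1 name in some libraries and under the other name in the rest. The pairs miR-27a-3p with miR-27b and miR-30f with miR-30c also switch in 1 library of each group, but less completely, and whether for the same reason was not tested. A change of cell state that acts on both miRNAs cannot be told apart from this, because miR-199a-3p held at least 99.4% of the summed reads in every adipocyte library and reassigning reads needs the sequences. The arm change of miR-199a rests on the same 3p counts.

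With library totals alone, 90.7% of the calls were higher in adipocytes. Leaving miR-21-5p out of the library size brought this to 53.3%, so the excess may come largely from the smaller share of miR-21-5p in adipocytes. A general rise of miRNAs in adipocytes cannot be told apart from it, since the median log2 difference of 0.62 under library totals has no outside standard to be set against.

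The DLK1-DIO3 list lay above 0 under every scaling, with a smallest median of 0.86, and had positive differences in 88.9% of its 18 families after summing. With the share of genome-feature reads as a covariate it stayed 1.21 above the other miRNAs, with a camera BH-adjusted p of 8.84e-11 at the preset correlation and 0.274 at an estimated one. With the covariate 14 members passed edgeR's threshold, against 7 without it, while the calls over all miRNAs rose from 26 to 63. Without the covariate the list was likewise not called at an estimated correlation (camera BH-adjusted p = 0.525), since its members vary together, and the preset correlation called it in 6 of the 10 splits of the 6 libraries. The median and the families argue against scaling and reads shared between its members as the whole source. Fragmented RNA in some preadipocyte libraries stays open, because the covariate test rests on the preset correlation and the called members rose along with all calls. The list's median was 1.66 without preadipocyte replicate 3, the library with the smallest share of genome-feature reads. It was 1.00 and 0.97 without preadipocyte replicates 1 and 2, which had the largest shares. The real split gave a difference of 1.32 and the highest other split 0.83. A higher output of the domain in adipocytes thus remains a hypothesis, and a domain-wide difference between cultures that is unrelated to induction stays open.

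There are 10 ways to split the 6 libraries into 3 and 3, too few for a share under 0.05. The real split called 26 miRNAs and the highest of the others 2, so that 1 of the 10 splits reached the real count. For arm usage the real split called 1 precursor and every other split 0, again 1 of 10. At least 1 list was called in 6 of the 10 splits, with 1 in the real split and 2 in the highest other.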
